A study of Mus musculus with 6 samples.

How the data were processed

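The series holds 6 RNA-seq libraries of group 3 innate lymphoid cells sorted from the small intestinal lamina propria of C57BL/6 mice aged 7 to 9 weeks, 3 labelled wild type with the floxed Bmal1 allele (WT) and 3 labelled with the floxed allele and Rorc-cre (KO). Per the labels, libraries were made from the sorted cells with the SMARTer ultra low input kit, which amplifies full-length cDNA and does not mark the strand, so reads from a gene and from an overlapping gene on the opposite strand cannot be separated. The labels number the samples within each genotype and do not state whether each number is a separate mouse, so p-values measure the spread between these samples.

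The authors deposited 1 table of raw read counts per gene, with whole numbers in 6 columns whose names match the samples, and no normalization was applied to it. The submitters' processing notes name CASAVA 1.8.2, STAR 2.3.0 and the genome build mm10. The program that counted the reads, its strand setting and the gene annotation are not given in the sources used here. The 27179 rows of the deposited count table are named by numeric gene identifiers, of which 25275 (93.0%) were matched to a symbol in a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 is built on. The remaining 1904 rows held 0.231% to 0.280% of the counts of a library. They stayed in the library totals and in the tests under their identifiers. Coordinates are 1-based positions of whole genes in GRCm38. The symbols of mitochondrially encoded mRNAs had no match, so that list was not tested.

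Library totals ran from 45031379 to 57513033 counts, a range of 1.28-fold. Libraries of a group were compared for duplicates by a chi-square statistic over genes with at least 10 counts in both. It ran from 87.4 to 476 per degree of freedom, far above sampling noise, and all 6 libraries were kept as separate samples.

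Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by edgeR's filterByExpr with the genotypes as groups, a minimum count of 10 and a minimum total of 15, which left 12474 genes. Library sizes were scaled by the trimmed mean of M-values (TMM). KO was compared with WT by the quasi-likelihood F test (glmQLFit and glmQLFTest) with genotype as the only term, on 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. All log2 fold changes are KO over WT. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM from edgeR's cpm function, given as mean ± SD. The median tagwise coefficient of variation between libraries of a genotype was 38.5%.

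The test, the covariates, the rule for named genes and 32 gene lists were fixed before the data were examined. The lists cover clock genes, ILC3 subsets, markers of other cell types that a sort could hold, and stress, signalling and metabolic programmes. Lists with at least 3 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists tested. Each list was also run with an estimated correlation and with fry, and its members were counted after adjustment over all genes and adjusted over the list alone. The erythroid list had 0 tested genes and the list of mast cells and basophils 2, so neither was tested. Named genes were Arntl, Rorc, Il22, Il17a, Il17f and 12 core clock genes whatever their result, then the 10 genes with the smallest p in each direction, and up to 4 members of each list with the smallest p. Genes named in each direction had to pass the threshold, have no overlap between the genotypes in CPM, average at least 5 CPM and carry a protein-coding or long non-coding gene symbol. A gene named outside this rule is said to have been chosen after its values were seen.

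The procedure was tested on simulated data for KO against WT, with 200 genes changed in each of 5 simulations over 12101 genes on average. It recovered 9.43% of 2-fold, 54.2% of 4-fold and 73.0% of 8-fold changes, and 5.73% of its calls were false. Changes near 2-fold were therefore mostly below what 3 libraries per genotype could detect. A shifted list was recovered by camera at the preset correlation in 5 of 5 simulations, with 0 other lists called. The simulated genes were drawn independently of each other, so this does not test lists whose members vary together. In the data the estimated correlation reached 0.778, for ribosomal protein genes.

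Alternatives were other scalings (the size factors of DESeq2, library size only), other filters (none, and at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with and without quality weights, the robust quasi-likelihood fit, the sample number as a block, the removal of sex-linked or ribosomal protein genes, a threshold of 0.1, and leaving out each library in turn. Leaving out both libraries numbered 1, or both numbered 3, was added after the data were seen. In each fit with libraries left out the filter was applied anew, so lists could hold other members than on all 6 libraries.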

Results

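Group 3 innate lymphoid cells (ILC3) are lymphocytes without rearranged antigen receptors that depend on the transcription factor RORγt, encoded by Rorc, and make interleukin 17 and interleukin 22. They were sorted from the small intestinal lamina propria of mice with a floxed Bmal1 gene and Cre recombinase driven by Rorc (KO, n = 3 libraries) and of littermates labelled with the floxed gene alone (WT, n = 3 libraries). BMAL1, whose gene carries the symbol Arntl in the annotation, pairs with CLOCK to activate E-box genes of the circadian clock. The comparison asks which ILC3 transcripts differ when this factor is deleted in cells that express Rorc. The deposited counts totalled 57513033, 45425139 and 50085901 in WT 1, WT 2 and WT 3. They totalled 45031379, 46919342 and 50482332 in KO 1, KO 2 and KO 3, with 14322 to 16174 genes detected per library. The first principal component of log2 CPM (28.2% of the variance) separated the genotypes, and the second (23.7%) set WT 1 and KO 1 apart from the other libraries. Xist, transcribed from the inactive X chromosome, was counted at 146 CPM in WT 3 and 105 CPM in KO 3 and at 0.0662 to 0.848 CPM in the other libraries. The Y-linked gene Ddx3y was at 1.58 and 1.32 CPM in WT 3 and KO 3 and at 357 to 566 CPM in the others. By these 2 genes each genotype held 1 female library, and its others were male. Sex was not a term in the test.

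The targeted gene Arntl (gene identifier 11865, chromosome 7, positions 113178471 to 113314126 of GRCm38) was counted at 96.3, 55.2 and 57.0 CPM in the WT libraries and at 61.5, 41.4 and 48.3 CPM in the KO libraries. Its log2 fold change of -0.46 (SE 0.28) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.831), and the ranges of the genotypes overlapped. Counts over the whole gene include reads from exons outside a deleted part, so this value does not check the genotype labels.

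The 2 REV-ERB genes, clock genes activated through E-boxes, fell in KO ILC3. Nr1d1, which encodes the repressor REV-ERBα, fell 17.1-fold from 117 ± 78.0 to 6.84 ± 1.60 CPM (SD, n = 3 per genotype). Nr1d2, which encodes REV-ERBβ, fell 6.54-fold from 287 ± 12.7 to 43.9 ± 11.5 CPM. Npas2, a paralogue of Clock that REV-ERB proteins repress, rose 6.98-fold from 5.30 ± 2.12 to 37.1 ± 1.32 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold changes were -4.09 (SE 0.49, adjusted p = 0.0110) for Nr1d1, -2.71 (SE 0.24, adjusted p = 0.00254) for Nr1d2 and 2.80 (SE 0.36, adjusted p = 0.0121) for Npas2. The tetraspanin gene Tspan4 also fell, by 3.28-fold (adjusted p = 0.0384). The PAR bZIP gene Dbp averaged 28.1 CPM in WT and 3.82 CPM in KO and missed the threshold (log2 fold change -2.88, SE 0.51, adjusted p = 0.0571). With the sample number as a block, Dbp passed (adjusted p = 0.0268). The values of Tef (-1.85, adjusted p = 0.216), Per3 (-4.15, adjusted p = 0.267), Ciart (-1.54, adjusted p = 0.398) and Per1 (-0.80, adjusted p = 0.668) were negative and did not pass, and the period gene Per2 had a log2 fold change of 0.60 (adjusted p = 0.973). Neither did Cry1 (0.89, adjusted p = 0.202), Gpr65 (0.78, adjusted p = 0.250), Clock (0.29, adjusted p = 0.915) or Nfil3 (-0.089, adjusted p = 0.998) pass.

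Of 17 tested members of the E-box list, 3 fell over all genes tested and 8 adjusted over the list alone, with 11 negative values and a median log2 fold change of -0.69. Camera placed the list below other genes (adjusted p = 1.45e-09), and the median was -0.46 without WT 1. With an estimated correlation, which was -0.044, the call was lost (camera adjusted p = 0.0607). That correlation lies below the preset 0.01, so members that vary together do not account for the loss. Fry also called this list lower (adjusted p = 0.00203). In the list of REV-ERB-repressed clock genes, Npas2 alone of 7 members rose over all genes and 3 members did adjusted over the list alone. The median of this list was 0.45 (camera adjusted p = 6.29e-05, adjusted p = 0.105 with an estimated correlation, here -0.056), and it was 0.74 without KO 1. Fry called the list higher (adjusted p = 0.0184). With 1 library left out, the log2 fold change of Nr1d1 ran from -4.36 to -3.39. The adjusted p of Nr1d1 was 0.0578, 0.0624 and 0.0730 without KO 1, KO 2 and KO 3, and that of Npas2 was 0.0863, 0.0578, 0.0597 and 0.0746 without WT 2, KO 1, KO 2 and KO 3. Tspan4 lost its call whichever of the 6 libraries was left out (adjusted p = 0.0696 to 0.221) and with the sample number as a block (adjusted p = 0.0544). Thra, Sphk2 and Chid1, which overlap Nr1d1, Dbp and Tspan4, averaged at most 14.9 CPM in either genotype and did not pass the test.

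**Figure D1:**
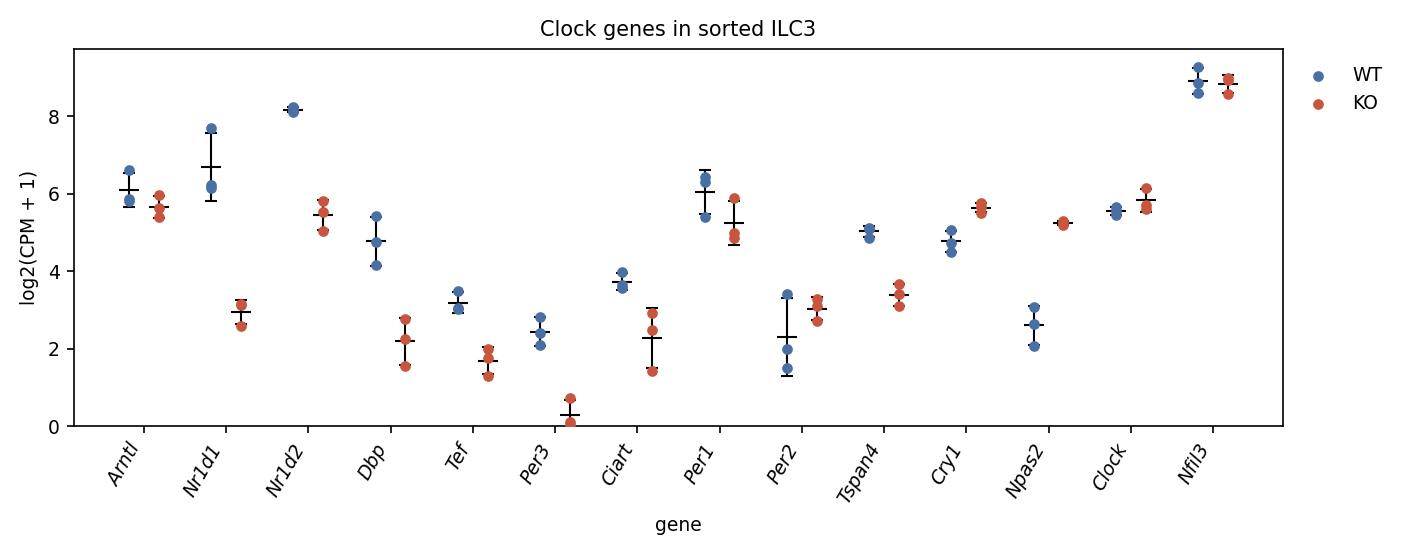
Levels of Arntl and of clock genes in each library, as log2(CPM + 1) on the vertical axis, with 1 point per library (WT blue, KO red, n = 3 each) and the mean ± SD of these log values in black. Every KO value of Nr1d1 and Nr1d2 lies below every WT value, every KO value of Npas2 lies above, and those of Arntl, Per1, Per2, Clock and Nfil3 overlap between genotypes.

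KO ILC3 had 59 genes at a higher level and 27 at a lower level than WT ILC3 among 12474 genes tested. Crybb2, a lens crystallin gene, went from 0.0893 ± 0.0114 to 58.9 ± 21.4 CPM (646-fold, adjusted p = 0.000418), and the matrix protein gene Spon2 from 0.110 ± 0.0602 to 105 ± 64.6 CPM (916-fold, adjusted p = 0.00181). These folds rest on 4 or 5 counts per WT library for Crybb2 and 2 to 8 for Spon2. The log2 fold change of Spon2 ran from 9.22 to 10.2 with 1 library left out. Srgap3, which encodes a Rho family GTPase-activating protein, rose 26.4-fold and the neutrophil chemokine gene Cxcl3 rose 11.3-fold, from 207 ± 73.9 to 2348 ± 391 CPM. The lipopolysaccharide co-receptor gene Cd14 rose 9.57-fold, the lysosomal enzyme gene Naga 6.59-fold, Igfbp7 4.85-fold, the urokinase receptor gene Plaur 4.09-fold and the adenosine kinase gene Adk 3.58-fold. Among genes that fell, the guanine deaminase gene Gda went from 37.6 ± 7.03 to 1.84 ± 0.402 CPM (20.4-fold, adjusted p = 0.00236) and the amino acid transporter gene Slc6a20a fell 10.3-fold. Ctsw, which encodes the cathepsin W of cytotoxic lymphocytes, fell 4.11-fold, the protease inhibitor gene Timp2 3.89-fold, the lactate dehydrogenase gene Ldhb 3.11-fold and the lectin-like receptor gene Klrb1f 2.92-fold.

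All 86 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, differed at least 2-fold and had no overlap between genotypes. Over all tested genes 14.5% had no such overlap, against 10% by chance for 3 against 3, and 1011 genes had an unadjusted p under 0.05. DESeq2 called 386 genes, 212 higher and 174 lower, which included the 86. The count was 67, 23 and 40 without WT 1, WT 2 and WT 3, and it was 36, 31 and 33 without KO 1, KO 2 and KO 3. Without both libraries that express Xist 4 genes passed, 3 of them among the 86 (Crybb2, Spon2 and Srgap3), while others such as Ncr1 (adjusted p = 0.0768) and Il17f (adjusted p = 0.111) did not. Limma-voom did not call Crybb2 (adjusted p = 0.130) or Spon2 (adjusted p = 0.239). Without WT 2 or KO 2 the calls of Ctsw, Klrb1f, Ldhb and Timp2 were lost, as were those of Ctsw, Klrb1f and Timp2 without KO 1, Klrb1f and Ldhb without KO 3 and Timp2 without WT 3 (adjusted p up to 0.0613, 0.0788, 0.0768 and 0.0739 for the 4 genes).

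Il17f and Il17a, which encode the cytokines IL-17F and IL-17A and lie next to each other on chromosome 1, were higher in KO ILC3. Il17f rose 13.7-fold, from 1313 ± 466 to 18039.6 ± 3665 CPM (SD, n = 3 per genotype), and Il17a rose 6.44-fold, from 25.5 ± 12.3 to 164 ± 53.9 CPM. Il22, the other signature cytokine gene, averaged 8005 ± 4222 CPM in WT and 10537 ± 4353 CPM in KO and overlapped between genotypes. Furin, which encodes a proprotein convertase, rose 4.19-fold and the matrix protein gene Chad fell 2.13-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold changes were 3.78 (SE 0.30, adjusted p = 0.00245) for Il17f, 2.69 (SE 0.43, adjusted p = 0.0369) for Il17a and 0.40 (SE 0.46, adjusted p = 0.978) for Il22. They were 2.07 (SE 0.25, adjusted p = 0.0110) for Furin and -1.09 (SE 0.18, adjusted p = 0.0432) for Chad. Over the 18 tested effector genes 3 rose and 1 fell, with the same counts adjusted over the list alone. The list as a whole was not called by camera (adjusted p = 0.279), and its median of -0.27 and its mean of 0.13 differed in sign. Beside these genes, the T cell receptor gene Trac averaged 24.4 ± 4.04 CPM in WT and 65.3 ± 20.9 CPM in KO (adjusted p = 0.0874). The adjusted p of Il17a was 0.163, 0.0791, 0.0985, 0.0883 and 0.135 without WT 2, WT 3, KO 1, KO 2 and KO 3. That of Furin was 0.0768, 0.0509 and 0.0552 without WT 2, KO 1 and KO 2, and that of Chad 0.0801 to 0.237 whichever library was left out.

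Genes of ILC3 identity gave 1 call among 27 members tested. The interleukin 2 receptor gene Il2ra fell 2.26-fold, from 463 ± 43.5 to 205 ± 39.3 CPM, and was also the 1 call adjusted over the list alone. Rorc itself averaged 419.7 ± 221 CPM in WT and 485 ± 185 CPM in KO. The receptor gene Kit averaged 358 and 244 CPM, the transcription factor gene Tox 103 and 174 CPM and the arginase gene Arg1 836 and 1323 CPM in WT and KO. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0470 for Il2ra, 0.998 for Rorc, 0.283 for Kit, 0.344 for Tox and 0.398 for Arg1. Camera did not call the identity list (median -0.031, adjusted p = 0.582). The list of lymphoid tissue inducer-like ILC3 held 2 genes that rose (Il17f and Il17a) and 1 that fell (Slc6a20a) among 12 tested, the same as adjusted over the list alone, with Ccr7 at 0.65 (adjusted p = 0.878), and was not called on all 6 libraries (camera adjusted p = 0.0783). It was called without WT 1 (adjusted p = 0.00513), without KO 3 (adjusted p = 0.00735) and on all 6 libraries with the sample number as a block (adjusted p = 0.00193). Il2ra lost its call whichever library was left out (adjusted p = 0.0883 to 0.244).

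Ncr1, Cd160 and Nkg7 fell in KO, among genes shared by ILC3 that carry natural cytotoxicity receptors (NCR), ILC1 and natural killer cells. Ncr1, which encodes the receptor NKp46, fell 6.76-fold, from 457 ± 67.5 to 67.6 ± 16.0 CPM (SD, n = 3 per genotype). Cd160, a receptor gene of cytotoxic lymphocytes, fell 4.74-fold, from 411 ± 33.1 to 86.8 ± 8.93 CPM, and the granule protein gene Nkg7 fell 3.77-fold, from 457 ± 78.4 to 121 ± 34.1 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold changes were -2.76 (SE 0.23, adjusted p = 0.00254) for Ncr1, -2.24 (SE 0.18, adjusted p = 0.00245) for Cd160 and -1.92 (SE 0.25, adjusted p = 0.0127) for Nkg7. Klrb1c, which encodes NK1.1, had a log2 fold change of -2.90 (SE 0.52) and did not pass (adjusted p = 0.0622), except without KO 2 (adjusted p = 0.0300) among the libraries left out in turn. With the sample number as a block, Klrb1c passed (adjusted p = 0.0181). Ncr1, Cd160 and Nkg7 were the 3 that passed among 27 tested over all genes, 10 were lower adjusted over the list alone, and 22 values were negative, with a median of -0.84. Camera placed the list below other genes (adjusted p = 2.91e-16), a call that was lost at adjusted p = 0.0607 with an estimated correlation. Fry also called this list lower (adjusted p = 0.0154). Cd160 lies within 5 Mb of Rorc on chromosome 3, and genes of the Klrb1 family are close paralogues whose reads the counting could split. The adjusted p of Nkg7 was 0.0697, 0.0583, 0.0592 and 0.0905 without WT 2, WT 3, KO 1 and KO 2.

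**Figure D2:**
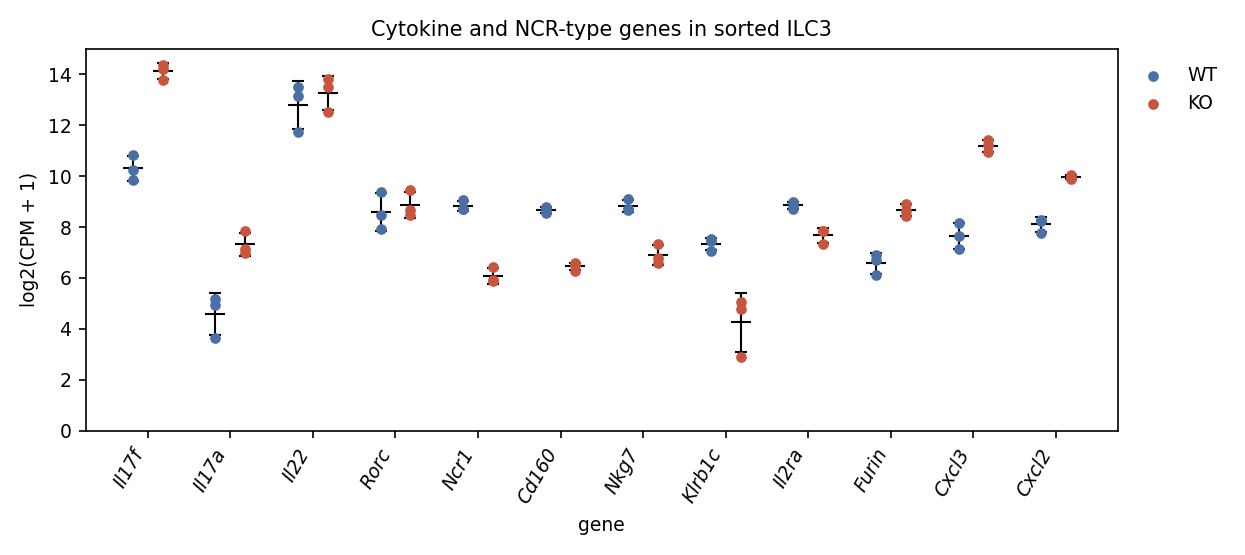
Levels of cytokine, receptor and NCR-type genes in each library, as log2(CPM + 1) on the vertical axis, with 1 point per library (WT blue, KO red, n = 3 each) and the mean ± SD of these log values in black. The KO values of Il17f, Il17a, Furin, Cxcl3 and Cxcl2 lie above all WT values, those of Ncr1, Cd160, Nkg7, Klrb1c and Il2ra lie below, and those of Il22 and Rorc overlap.

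Among markers of epithelium and stroma, cells that a sort could hold, 1 gene (Igfbp7) passed over all genes. The filter on low counts kept 8 of 36 epithelial markers and 5 of 20 markers of stroma and endothelium. Igfbp7 itself was at 104 to 122 CPM in the WT libraries. In the epithelial list, the Paneth cell defensin gene Defa24 was counted at 14.0, 2.76 and 27.4 CPM in the KO libraries and at most 0.202 CPM in WT, and its relative Defa30 averaged 3.61 CPM in KO and 0.0224 CPM in WT. Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0621 and 0.107), and defensin genes are near-identical copies whose counts are uncertain. With the sample number as a block, Defa24 passed (adjusted p = 0.00920). Of 8 epithelial genes 0 passed over all genes, 3 were higher adjusted over the list alone and at unadjusted p under 0.05, and DESeq2 called 2. Camera placed the list higher (median 3.11, adjusted p = 2.3e-05, adjusted p = 0.215 with an estimated correlation), and the median was 4.81, 6.42 and 7.08 without WT 1, WT 2 and WT 3. The filter, applied anew, left 12940, 13029 and 12959 genes in these fits, so the medians could cover other genes than the 8. Of 5 genes of stroma and endothelium Igfbp7 rose, while 2 were higher and 1 lower adjusted over the list alone. Pdgfrb, a pericyte receptor gene, averaged 9.96 CPM in WT and 34.1 CPM in KO (adjusted p = 0.147, or 0.0452 with the sample number as a block). Camera placed the stroma list higher (median 1.39, adjusted p = 0.000549, adjusted p = 0.218 with an estimated correlation), but not without WT 1 (median 0.45, adjusted p = 0.211) or with no filter on low counts (median -0.080, adjusted p = 0.147). The median was 0.65 without KO 2 and 0.67 without KO 3.

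Immunoglobulin transcripts of plasma cells varied between KO libraries. Jchain, Igha, Igkc and Iglc1 together reached 2682, 21.9 and 493 CPM in KO 1, KO 2 and KO 3, and 7.29 to 9.10 CPM in the WT libraries. None passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.134, 0.138, 0.208 and 0.288), except Jchain without KO 2 (adjusted p = 0.0466). Of 9 B and plasma cell genes 0 passed over all genes, 5 were higher and 1 lower both adjusted over the list alone and at unadjusted p under 0.05, and DESeq2 called 2. Camera did not call this list on all 6 libraries (median 0.78, adjusted p = 0.0734) but did without WT 2, KO 2 or KO 3 (medians 4.04, 3.01 and 0.95, adjusted p = 0.0131, 7.74e-07 and 0.0158). With the sample number as a block, camera called this list too (adjusted p = 0.0405). Of 15 T cell genes 0 passed, 3 were higher and 2 lower adjusted over the list alone, DESeq2 called 2 in each direction, and camera did not call the list (median 0.53, adjusted p = 0.122). The genes with the smallest p in it were Ctla4, at 198 CPM in WT and 63.1 CPM in KO, and Trac. Among 14 myeloid genes Cd14 alone rose, which was also the case adjusted over the list alone. Camera did not call the myeloid list on all 6 libraries (median 0.19, adjusted p = 0.0655) but did without WT 2, WT 3 or KO 1 (medians -0.024, 1.79 and 0.67, adjusted p = 0.0450, 0.000417 and 0.000796). In these fits, as in those of the B and plasma cell list, the members tested could differ. Of 9 ILC2 genes 0 passed over all genes, 0 adjusted over the list alone and 0 by DESeq2, with 2 at unadjusted p under 0.05 (camera adjusted p = 0.760).

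Of the programmes of stress, growth and signalling, heat shock genes had positive values in 17 of 17 tested members. Their median log2 fold change was 0.60, 0 passed over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 2. The co-chaperone gene Dnaja1, with the smallest p, averaged 543 ± 20.7 CPM in WT and 863 ± 125 CPM in KO (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.185). Camera placed this list higher (adjusted p = 1.75e-05, adjusted p = 0.403 with an estimated correlation), and its median was 0.25 without KO 1. Its members summed to 6965 CPM in WT 1 and 8661 CPM in KO 1, against 3944 and 4387 CPM in the other WT libraries and 5627 and 6024 CPM in the other KO libraries. Immediate early genes, which tissue dissociation also raises, summed to 22647 CPM in WT 1 and 19301 CPM in KO 1 against 8214 to 10801 CPM in the other libraries. Of 31 such genes 0 passed over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05 and DESeq2 called 2. Camera did not call the list (median 0.015, adjusted p = 0.345), but placed it higher without WT 1 (median 0.64, adjusted p = 0.000109) and without KO 2 (median 0.27, adjusted p = 0.0274).

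Cell cycle genes had a median of 0.76 over 32 members, with 27 positive values. Camera placed them higher (adjusted p = 0.000549, adjusted p = 0.480 with an estimated correlation) but not without WT 3 (adjusted p = 0.0620). Relative to the WT mean, their mean log2 CPM was 0.53, 0.59 and -1.12 in WT 1, WT 2 and WT 3. It was 0.58, 1.24 and 1.13 in KO 1, KO 2 and KO 3, so KO 1 was level with WT 1 and WT 2. By edgeR 0 passed over all genes or adjusted over the list alone, with 4 at unadjusted p under 0.05 and 1, in the lower direction, by DESeq2. Ribosomal protein genes had a median of 0.29 over 79 members, 72 of them positive (camera adjusted p = 2.3e-05, adjusted p = 0.665 with an estimated correlation). This call was lost without WT 1 (median 0.094, adjusted p = 0.253). In this list 0 members passed over all genes, adjusted over the list alone or by DESeq2, and 2 had an unadjusted p under 0.05. Genes of the unfolded protein response had a median of 0.22 over 23 members (camera adjusted p = 0.0157, adjusted p = 0.403 with an estimated correlation). Of them 0 passed over all genes and 1 did adjusted over the list alone, namely Ddit4 at 0.435 CPM in WT and 6.85 CPM in KO, while 2 had an unadjusted p under 0.05 and DESeq2 called 1. That list was not called without WT 3 (adjusted p = 0.0840) or KO 3 (median 0.12, adjusted p = 0.108).

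Interferon response genes included 2 that rose, Oasl2 by 3.35-fold (33.1 ± 4.48 to 111 ± 20.6 CPM, adjusted p = 0.0122) and the chemokine gene Cxcl10 by 2.29-fold (602 ± 129 to 1380 ± 80.4 CPM, adjusted p = 0.0380), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over the 34 interferon genes tested 2 were higher and 1 lower adjusted over the list alone. The lower gene was Ifit3, at 1.62 CPM in WT and 0.00753 CPM in KO, which did not pass over all genes (edgeR adjusted p = 0.0909). Irf7 averaged 271 CPM in WT and 131 CPM in KO and did not pass either (edgeR adjusted p = 0.396). Camera placed the list higher (median 0.33, adjusted p = 0.0220, adjusted p = 0.480 with an estimated correlation), though not without KO 2 (median 0.16, adjusted p = 0.108) or KO 3 (adjusted p = 0.143). Among 23 NF-κB targets the neutrophil chemokine gene Cxcl2 rose 3.60-fold, from 277 ± 53.3 to 997 ± 57.5 CPM, and Cxcl10 rose, while 3 were higher and 2 lower adjusted over the list alone. In that list Ccl4 averaged 186 CPM in WT and 7.36 CPM in KO without passing (adjusted p = 0.122), and camera did not call it (adjusted p = 0.337). The cell cycle inhibitor gene Cdkn1a rose 2.17-fold, from 981 ± 98.5 to 2126 ± 166 CPM, as the 1 call among 17 p53 targets over all genes and adjusted over the list alone (camera adjusted p = 0.274). The complex I gene Ndufa1 rose 4.78-fold, from 424 ± 139 to 2025 ± 837 CPM, as the 1 call in both counts among 55 nuclear genes of oxidative phosphorylation, whose median was 0.012 (camera adjusted p = 0.345). Lpl, which encodes lipoprotein lipase, rose as the 1 call in both counts among 38 lipid genes (camera adjusted p = 0.357), with 5.30 ± 2.10 CPM in KO and 1 count over the WT libraries, and was not called by limma-voom (adjusted p = 0.0982). With 1 library left out, Cxcl10 kept its call only without WT 3, Cdkn1a and Lpl only without WT 1 and Ndufa1 only without KO 1, and Oasl2 lost it without WT 2, KO 2 and KO 3. The highest adjusted p among these fits was 0.237, 0.165, 0.0803, 0.226 and 0.105 for Cxcl10, Cdkn1a, Lpl, Ndufa1 and Oasl2.

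The other lists were not called by camera on all 6 libraries and had 0 members past the threshold over all genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among 29 apoptosis genes the pro-apoptotic Bcl2l11 was higher and the death ligand gene Fasl lower adjusted over the list alone, with log2 fold changes of 0.91 and -2.41. In that list 3 genes had an unadjusted p under 0.05 and DESeq2 called 3 (camera adjusted p = 0.760). Among 22 homing receptors the gut-homing receptor gene Ccr9 had a log2 fold change of -2.01 (SE 0.51, adjusted p = 0.185), with 0 members passing adjusted over the list alone, 4 at unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.179). Without KO 3, Ccr9 (adjusted p = 0.0408) and Fasl (adjusted p = 0.0237) passed. Vegfa, among 26 genes of glycolysis and hypoxia, and Srxn1, among 21 oxidative stress genes, were each the 1 gene higher adjusted over the list alone, with log2 fold changes of 1.07 and 0.84. Their lists had camera adjusted p of 0.593 and 0.109, with 3 and 5 members at unadjusted p under 0.05 and 1 each by DESeq2. Glucocorticoid response genes gave 1 higher adjusted over the list alone (Ddit4) among 13, with a median of -0.38, 4 at unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.145). The 12 genes of MHC class II presentation gave 0 in all of these counts (median 0.41, camera adjusted p = 0.279) and so did the 5 sex-linked genes (camera adjusted p = 0.970). With 1 library left out, camera called homing receptors without WT 2 (adjusted p = 0.0411) and the glucocorticoid and MHC class II lists without KO 1 (adjusted p = 0.0390 and 0.000796). With the sample number as a block, camera called the glucocorticoid and oxidative stress lists (adjusted p = 0.0298 for each). Of 29 lists camera called 10, of which 8 were higher and 2 lower in KO. With an estimated correlation 0 were called, 5 having an unadjusted p under 0.05.

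**Figure D3:**
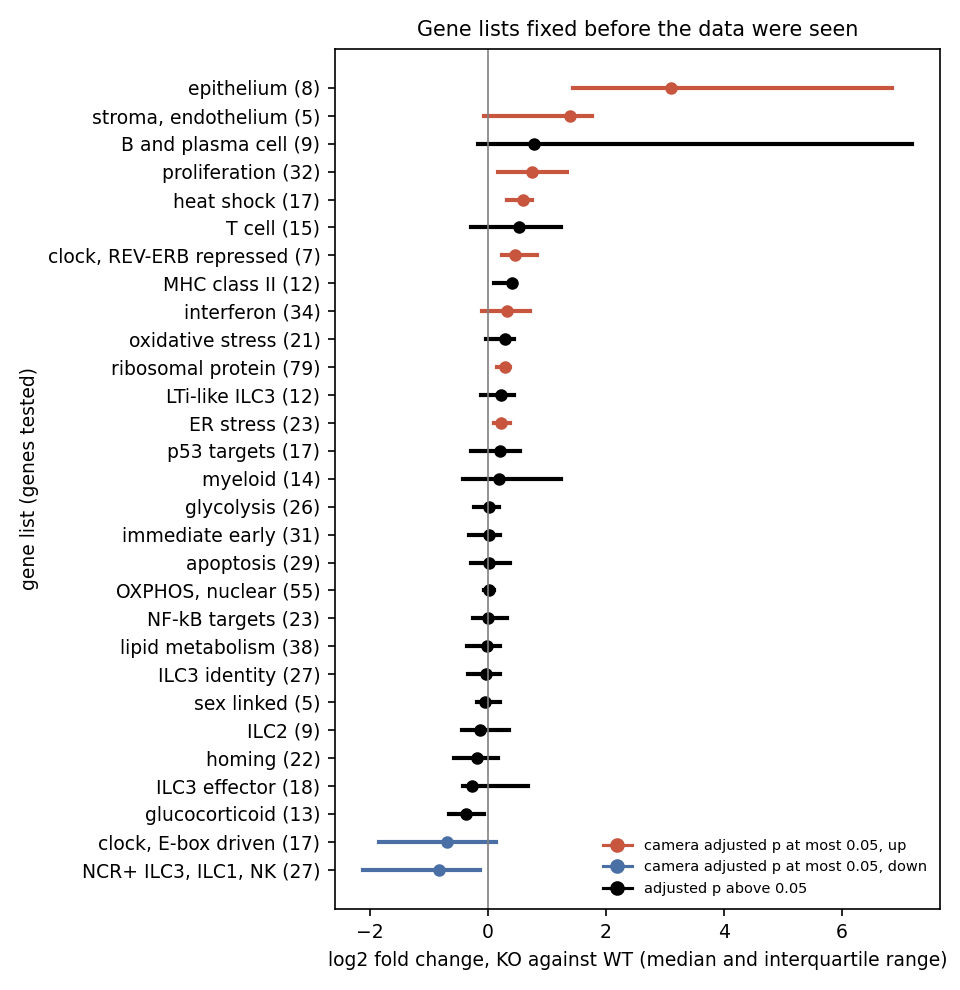
Median (point) and interquartile range (line) of the log2 fold changes, KO against WT, of the tested members of each of 29 gene lists, with the number of genes tested in parentheses on the vertical axis. Red and blue mark the 8 lists placed higher and the 2 placed lower by camera at the preset correlation, with the NCR list at a median of -0.84 and the E-box clock list at -0.69. With an estimated correlation 0 lists were called.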

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

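Leaving out both libraries numbered 1 or both numbered 3 was chosen after the data were seen. All 86 changed genes kept their direction in every alternative fit, which their lack of overlap between the genotypes largely fixed in advance. Against 86 genes (59 higher, 27 lower), the count was 148 with no filter (94 and 54), 386 with DESeq2 (212 and 174, or 54.9% higher against 68.6%), 142 with limma-voom and quality weights (54 lower), 140 at a threshold of 0.1 (54 lower) and 4 without both libraries numbered 3 (4 and 0; 777 genes had an unadjusted p under 0.05). With 1 library left out it ran from 23 to 67, with 17 to 47 higher and 6 to 20 lower; fewer libraries leave less power, and the other causes were not tested. Without both libraries numbered 1 the count was 69, against 4 without both numbered 3, so it depended on which libraries were left out and not only on how many. The other fits gave 80 to 105 genes. With the sample number as a replicate block, 130 genes passed (86 higher, 44 lower), 79 of them among the 86, and 14 lists were called. Under the block Tspan4 did not pass (adjusted p = 0.0544), while Dbp (0.0268), Klrb1c (0.0181), Defa24 (0.00920), Pdgfrb (0.0452) and the lists of B and plasma cells (0.0405), glucocorticoid response (0.0298), lymphoid tissue inducer-like ILC3 (0.00193) and oxidative stress (0.0298) did. Correlations across all tested genes of deviations from the genotype mean were 0.216, 0.0826 and 0.0423 for samples numbered 1, 2 and 3, so the numbers were not taken to pair the samples. Above 32 CPM the correlations were 0.613, 0.422 and 0.389 and each sample correlated best with its own number, a hint from the data and not the design, so a shared day or litter stays open. Without both libraries numbered 1, Mmp9 (adjusted p = 0.0597), Ctsw (0.0590), Tspan4 (0.0620), Il15 (0.0682), Cxcl10 (0.0829), Klrb1a (0.0872), S100a6 (0.0889), Il2ra (0.104), Lpl (0.116) and the stroma and endothelium list (0.0807) did not pass, and with the size factors of DESeq2 Il2ra did not (0.0501). Without both libraries numbered 3, camera did not call the cell cycle (adjusted p = 0.284), unfolded protein response (0.284) and interferon lists (0.153). Gene lists called numbered 10, 0 with an estimated correlation and 3 with fry, namely the E-box, REV-ERB-repressed and NCR lists. Arntl kept its sign and did not pass in any fit (-0.63 to -0.16). Only values that did not pass on all 6 libraries reversed, apart from the stroma and endothelium list, at -0.080 with no filter (camera adjusted p = 0.147). The myeloid list, not called on all 6 libraries, reversed to -0.024 without WT 2, where camera called it (adjusted p = 0.0450). With 1 library left out, Rorc ran from -0.15 to 0.71, Nfil3 from -0.23 to 0.11, Ccr6 from -0.46 to 0.38, Cd4 from -0.30 to 0.59 and the myeloid list from -0.26 to 1.79; without both libraries numbered 1, Nfil3 was at 0.063 and Ccr6 at 0.10. The cause of these reversals was not tested, and with libraries left out the list medians could cover other genes, since the filter was applied anew. At 45031379 to 57513033 counts per library, 9.43% of simulated 2-fold changes were recovered.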

Other observations

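The tests in this part, apart from the splits of the libraries, were chosen after the results were seen, as were the genes named in the next paragraph.

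Changed genes outside the fixed lists included the gelatinase gene Mmp9 (log2 fold change 5.95, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00808), the prostaglandin E synthase gene Ptges (2.10, adjusted p = 0.0115) and the calcium-binding protein gene S100a4 (2.07, adjusted p = 0.00767), all higher in KO. Lower in KO were the cytokine gene Il15 (-2.34, adjusted p = 0.0187) and the lectin-like receptor gene Klrb1a (-4.07, adjusted p = 0.0153, not called by limma-voom at adjusted p = 0.0641). In all 5 genes the 3 KO values lay on one side of the 3 WT values. With 1 library left out, Mmp9 kept its call in 6 of 6 fits, S100a4 lost it without WT 2 (adjusted p = 0.0662), Ptges in all but the fit without WT 1 (up to 0.0777), Klrb1a in all but the fit without KO 3 (up to 0.105) and Il15 in all 6 (0.0525 to 0.113).

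The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of the 10, the split by genotype, gave 86 genes. The highest count of any other split was 0 by edgeR's quasi-likelihood test, with 148 to 1055 genes at an unadjusted p under 0.05. The split by genotype had 1011 such genes, fewer than WT 1, WT 2 and KO 1 against the rest (1055). It also had fewer than WT 1, KO 1 and KO 3 against the rest (1013). Every other split mixes the genotypes within its groups, so differences by genotype widen the spread there and lower its count. With 10 splits no share under 0.05 can be reached.

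The lower values of NCR-type genes may reflect fewer NCR-bearing or type 1 cells in the KO sort, or less of these transcripts per cell. If such cells were fewer, markers of the complementary CCR6-positive subset should rise together, and the median log2 fold change of Ccr6, Cd4, Nrp1 and Cxcr5 was 0.018 with an SD of 0.286 over the 4 genes. That median decides nothing, so cell makeup and expression per cell cannot be told apart for these genes in counts from whole sorted populations. WT 1 and KO 1, the libraries with the most immediate early transcripts, are 1 of each genotype, so handling shared by both would weigh on both genotypes. Leaving out both cannot test such handling for Ncr1, Cd160 and Nkg7. All KO values of these genes lay below all WT values, so a fall had to remain. Without both, their log2 fold changes were -2.72, -2.23 and -1.84 (adjusted p = 0.0183, 0.00710 and 0.0488), against -2.76, -2.24 and -1.92 on all 6 libraries. For the list as a whole, handling was not decided either. Without both, the NCR list had a median of -0.64 with an SD of 2.39. It passed camera at the preset correlation (adjusted p = 6.69e-14) but not at an estimated one (adjusted p = 0.425), where the list did not pass on all 6 libraries either (adjusted p = 0.0607). An effect of the genotype on ILC3 themselves stays open too as a hypothesis.

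The rise of Il17f and Il17a could come from T cells in the KO sort, since some T cells make both cytokines, although a gate on ILC3 should remove T cells. The T cell list had a median log2 fold change of 0.53 with an SD of 2.35 and a camera adjusted p of 0.122, with 10 positive and 5 negative values. Adjusted over the list alone, 3 genes were higher (Trac, Trgc1 and Themis) and 2 lower, among them Ctla4. Themis, at 0 counts in WT, had a log2 fold change of 8.33, which widens the SD. The explanation by T cells thus stays open. Several genes of that list are also transcribed by ILC3. Trac averaged 65.3 CPM in KO, while Il17f averaged 18039.6 CPM. A change in ILC3 themselves with the genotype also stays open, untested by these counts.

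The immunoglobulin transcripts of KO 1 and KO 3 do not look like free RNA from 1 shared pool, in which the ratio of KO 1 to KO 3 would be alike for all genes. That ratio was 15.1 for Igha, 74.9 for Igkc and 0.0212 for Iglc1, so the highest of these was 3524 times the lowest. Igkc took 99.4% (95% exact binomial interval 99.3% to 99.5%) of the Igkc and Iglc1 counts in KO 1 and 4.57% (4.27% to 4.89%) in KO 3, with intervals for counting error only. Igkc also had more counts than Iglc1 in WT 1 (152 against 4), WT 2 (160 against 23), WT 3 (145 against 74) and KO 2 (332 against 29). The direction in KO 1 was therefore not particular to it, and KO 3 alone departed from it. A candidate explanation is a few plasma cells of different light chain in single libraries, which a gate on ILC3 should remove. Free RNA from a separate pool in each library was not tested. No explanation through the genotype was tested, and related light chain genes could share reads.

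Within 5 Mb of Rorc or Arntl lay 3 changed genes (S100a4, S100a6 and Cd160, all near Rorc), against 1.14 expected from the share of tested genes there (one-sided exact hypergeometric test, p = 0.106). The Rorc window held 119 tested genes and the Arntl window 42, of which 0 changed. Both genotypes are labelled with the floxed gene, so DNA carried with that allele would not differ between them. The Arntl window thus dilutes this test, and the Rorc window alone was not tested. With 1 library left out, S100a6 lost its call in all 6 fits (adjusted p = 0.0544 to 0.213) and S100a4 lost it without WT 2 (adjusted p = 0.0662). Changed genes formed 4 neighbouring pairs within 200 kb, namely Il17a with Il17f, S100a4 with S100a6, Cxcl3 with Cxcl2 and Man2a2 with Furin, where 10000 random draws of tested genes gave a median of 2 and a highest count of 10, with as many pairs or more at p = 0.126 by this one-sided permutation test.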
